A study of Saccharomyces cerevisiae with 62 samples.

How the data were processed

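Ribosome footprints (RNase I), mRNA (a stranded kit, single-end), poly(A) tails (single-molecule sequencing on the PacBio platform from the same total RNA) and capped 5′ ends (nAnT-iCAGE) were measured in 62 libraries of budding yeast, grouped by assay, strain and treatment as the labels give them. Footprint and RNA values were deposited as raw read counts for each gene, over the transcript and over the coding sequence, per the file headers. Per the file headers, a pair of further tables holds raw counts for genes and 92 ERCC spike-in RNAs, with the strains labelled dcp2Δ in a table of their own. SM-PAT values were deposited as molecule counts for each gene and the tail length of every molecule in nt, per the file headers, and no listed tail is under 12 nt. The CAGE values that the authors deposited are scaled tags (TPM, a CPM unit) for 1043197 positions of the genome, although the table is named as raw counts. Every CAGE value is a whole multiple of a step, within 0.1 tag, and the smallest is 3 tags, except in pab1-AID NAA replicates 2 and 3, where it is 2. Positions with fewer tags are absent from the values, and no step that removed them is stated. Bowtie2, HISAT2 2.1.1, SAMtools 1.9, STAR and minimap2, with the builds sacCer3 and R64, are named in the submitters' processing notes, and which tool served which assay is not given in the sources used here. How reads shared by near-identical genes were assigned is likewise not given, and 231 of 5366 genes were marked as sharing reads.

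Of 7072 entries in the gene files, 397 noncoding ones were left out because the comparisons concern coding genes. The 6675 kept hold 103 transposon reading frames, and 6001 matched the reference annotation (R64), from which 5280 symbols were taken. Counts over the coding sequence were tested with edgeR 4.0.16 by its robust quasi-likelihood test, with TMM factors and the filterByExpr filter, all groups of an assay sharing an estimate of the spread. Levels are TMM-scaled CPM. Relative translational efficiency was tested as the interaction of assay and condition in a joint fit, and differences of effects as interaction contrasts. Mean tail length was tested with limma 3.58.1 (trend and robust) for genes with at least 20 molecules in every library. CAGE values had been planned as counts for edgeR. Since they are scaled values, limma was used instead, on log2 of the value over the upstream TMM factor plus 1, with count tests on recovered tags as alternatives. Upstream tags lie within 500 nt before the start of a gene and internal tags from 100 nt inside it to its end, introns included, for 5986 genes. Yeast RNA relative to the spike-in was the ratio of gene counts to ERCC counts in a library, compared within each spike-in table. The internal test compares the internal change with the upstream change of the same gene. Adjusted p values are two-sided with Benjamini-Hochberg adjustment at 0.05. Single values per library were compared by two-sided exact permutation tests, for which the smallest p is 0.1 with 3 against 3 and 0.333 with 2 against 2. The 25 gene lists were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation. A total of 181 of 492 list tests passed and 14 of these held with an estimated correlation. Software also included DESeq2 1.42.0, R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

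Groups, tests (except that for CAGE values), most alternatives, gene lists and the rule for named genes were chosen before the data were examined. The rule takes the targeted genes, then the 6 largest called changes each way for the main comparisons and 3 each way for the others (6 rises for internal CAGE tags). It asks for a standard symbol, a level at or above the median of tested genes and replicate values of the groups that do not overlap. From each list described it takes the 4 called members with the largest change, and the lists to describe were picked after their results were seen. Not all list members so taken are given, and a gene so taken is not reported here. The alternatives covered DESeq2 and RLE scaling, spike-in totals as library sizes, other filters, fits of the compared groups alone, blocks by replicate number, molecule minimums of 10 and 50, other CAGE windows and tag minimums, and each replicate left out in turn. Further alternatives were added after the files were seen, such as the whole-transcript counts, leaving out transposon reading frames or those of the ribosomal DNA locus, and CAGE pseudocounts of 0.25 and 4.

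The tests were tried on simulated data with 200 changed genes. For Pab1 depletion, 62% of changes of 0.5 (log2) and 92% of changes of 1 were recovered in RNA (5962 genes), 77.8 and 95% in footprints (5603 genes) and 42 and 88% in translational efficiency (5580 genes). For tails 17% of changes of 6 nt and 98% of 20 nt were recovered (2175 genes; the sizes were raised from 3 and 6 nt after low recovery was seen), and for internal CAGE 16% of changes of 1 and 89% of 2 (4932 genes). False calls were 4.35, 4.44, 6.47, 6.50 and 6.25% of calls in that order. In the simulation all groups shared the mean level of a gene, and fewer genes changed than were called for Pab1 depletion in the data. CAGE counts were drawn around the mean over all CAGE libraries, the spt6 mutant included, with a preset spread. These rates need not hold in the data. Depth differed between libraries: footprint totals ran from 5902455 (pab1-AID NAA replicate 3) to 15304378 (pab1-AID KOH replicate 1), and RNA totals from 8559953 (dcp2Δ replicate 2) to 94605048 (wild-type KOH replicate 1), with 8658716 in pab1-AID NAA replicate 2. SM-PAT libraries held 321827 (wild-type NAA replicate 3) to 1046744 molecules (dcp2Δ replicate 2), and CAGE libraries 9842431 (pab1-AID NAA replicate 3) to 19662505 tags (replicate 2 of the wild type for set1Δ set2Δ), as implied by the step of their values. Preculture before treatment was labelled as 3 h for wild type, 4 h for pab1-AID in KOH and until a division for the others, so it differs with the groups. Replicate numbers were not used as a block, since they did not pair the libraries across groups. The labels name the same total RNA samples for several assays and do not state that the numbers match. No pair of footprint libraries and no pair of RNA libraries was identical, and the other assays were not checked for this.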

Results

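Budding yeast mRNAs were measured in 62 libraries that fall into 22 groups. Ribosome footprints and mRNA (stranded mRNA kit) were sequenced from 6 kinds of culture with 3 replicates each, 18 libraries per assay. Wild-type cells were of W303 background with the plant receptor OsTIR1. In pab1-AID cells the poly(A)-binding protein Pab1 carries an auxin-inducible degron. Both were kept for 6 h in 1 mM NAA, an auxin analogue, or in 1 mM KOH as control. The other libraries are labelled dcp2Δ and dcp2Δ pab1-AID, both in NAA, Dcp2 being the catalytic subunit of the decapping enzyme. Poly(A) tails were read on single molecules (SM-PAT) in the 4 groups with NAA, 3 replicates each. Capped 5′ ends were mapped by CAGE in 14 libraries. These held wild type and pab1-AID in NAA (3 each), a mutant of SPT6, a histone chaperone gene, whose allele stands on the axis of the plot of internal tag shares, with its wild type (2 each, shifted to 39 °C for 90 min), and set1Δ set2Δ, which lacks a pair of histone methyltransferases, with its wild type (2 each). Totals ran from 5902455 to 15304378 counts per footprint library and from 8559953 to 94605048 per RNA library. They ran from 321827 to 1046744 molecules per tail library and from 9842431 to 19662505 implied tags per CAGE library. The RNA libraries differed in make-up. Transposon reading frames took 49.2 to 67.7% of RNA counts in wild-type and pab1-AID libraries and 21 to 30.6% in those labelled dcp2Δ, where totals did not exceed 30248180.

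The targeted genes check the labels. PAB1 (YER165W) mRNA stood at 956 ± 26.6 CPM in wild type in KOH and 957 ± 2.35 in NAA, against 465 ± 26.8 in pab1-AID in KOH and 234 ± 10.3 in NAA (SD, n = 3). Libraries labelled dcp2Δ held 147 ± 8.80 and those labelled dcp2Δ pab1-AID 89.0 ± 4.63. PAB1 footprints were 1597 in wild type in NAA, 587 in pab1-AID in NAA, 617 in dcp2Δ and 381 in dcp2Δ pab1-AID. PAB1 mRNA was already lower with the tag alone, at a log2 change of -1.04 ± 0.07 (SE; edgeR, Benjamini-Hochberg adjusted p = 8.69e-10). The degron acts on the protein, whose loss RNA does not check. DCP2 (YNL118C) reads did not disappear from the libraries labelled dcp2Δ. DCP2 RNA was 98.6 ± 5.79 in wild type and 86.0 ± 8.58 in dcp2Δ, a change of -0.20 ± 0.099 that did not pass (edgeR, Benjamini-Hochberg adjusted p = 0.0783). Without dcp2Δ replicate 3 it passed (-0.27; edgeR, Benjamini-Hochberg adjusted p = 0.0309). DCP2 footprints were 83.6 and 266.5. HIS3 (YOR202W), the marker that the labels place at the deletion, rose from 5.81 ± 0.826 to 36 ± 2.30 in RNA and from 6.90 to 98.6 in footprints. In CAGE, tags upstream of SET1 (YHR119W) were 32.2 TPM in the wild type and 0.187 in set1Δ set2Δ, and those of SET2 (YJL168C) 26.7 and 2.24. SPT6 (YGR116W) had 129 TPM upstream in its wild type and 11.6 ± 1.87 in the spt6 mutant, while tags inside the gene were 1.17 ± 0.0603 and 58.3 ± 1.03 (SD, n = 2).

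Mating-type genes separated the libraries labelled dcp2Δ from the wild type, although the labels call both MATa. MF(ALPHA)1 (YPL187W, chromosome XVI, 193648 to 194145 in R64), which encodes the pheromone of α cells, was at 0.134 CPM in wild-type RNA and at 626 in dcp2Δ and 541 in dcp2Δ pab1-AID. STE3, the α-cell pheromone receptor, went from 6.04 to 33.2 and 42.9, and the α-agglutinin gene SAG1 from 33.8 to 124 and 234. In the other direction STE2, the a-cell receptor, was at 307 in wild type and at 6.82 and 7.41 in those libraries, the a-agglutinin subunit AGA2 at 59.1, 0.147 and 0.174, and the α-factor protease BAR1 at 94.2, 4.05 and 5.87. Footprints showed the same split, with MF(ALPHA)1 at 0.156, 1120 and 860 and STE2 at 143, 0.129 and 0.136. All 6 MATa-specific genes measured fell in RNA and all 5 MATalpha-specific genes rose in libraries labelled dcp2Δ against wild type, 6 and 5 adjusted over the list alone. Both calls held (limma's camera with Benjamini-Hochberg adjustment, adjusted p = 3.69e-11 and 3.61e-08; adjusted p = 0.000299 and 0.00229 with an estimated correlation). The CAGE pair of the spt6 mutant and its wild type, labelled MATα, carried an a pattern. STE2 stood at 692 TPM in the wild type and 1740 in the mutant, AGA2 at 210 and 197, and MF(ALPHA)1 at 0.466 and 2.67. Differences between dcp2Δ and wild type, given later, go with this split, with RNA depth and with a separate spike-in table, and cannot be told apart from them.

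How much mRNA a culture held per amount of added spike-in RNA was asked first for Pab1 depletion. Yeast reads per spike-in read were 65.5 ± 8.32 in wild type in KOH, 61.5 ± 2.45 in wild type in NAA, 58.1 ± 8.10 in pab1-AID in KOH and 44.4 ± 6.35 in pab1-AID in NAA (SD, n = 3). All 3 depleted libraries lay below all 3 wild-type libraries in NAA, a log2 difference of -0.48 or a change of -28.3% (two-sided exact permutation test, p = 0.1, the smallest that 3 against 3 allows). Against pab1-AID in KOH the change was -23.7% (log2 -0.39, exact p = 0.1). NAA in wild type gave -0.08 (exact p = 0.7) and the tag -0.17 (exact p = 0.4). In the separate table of the other strains the ratio was 134.7 ± 17.2 in dcp2Δ and 133 ± 11.4 in dcp2Δ pab1-AID, a log2 difference of -0.01 (exact p = 0.9), with 4.42 to 10.3% of counts there in reading frames of the ribosomal DNA locus. Ratios of the 2 tables were not compared.

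**Figure D1:**
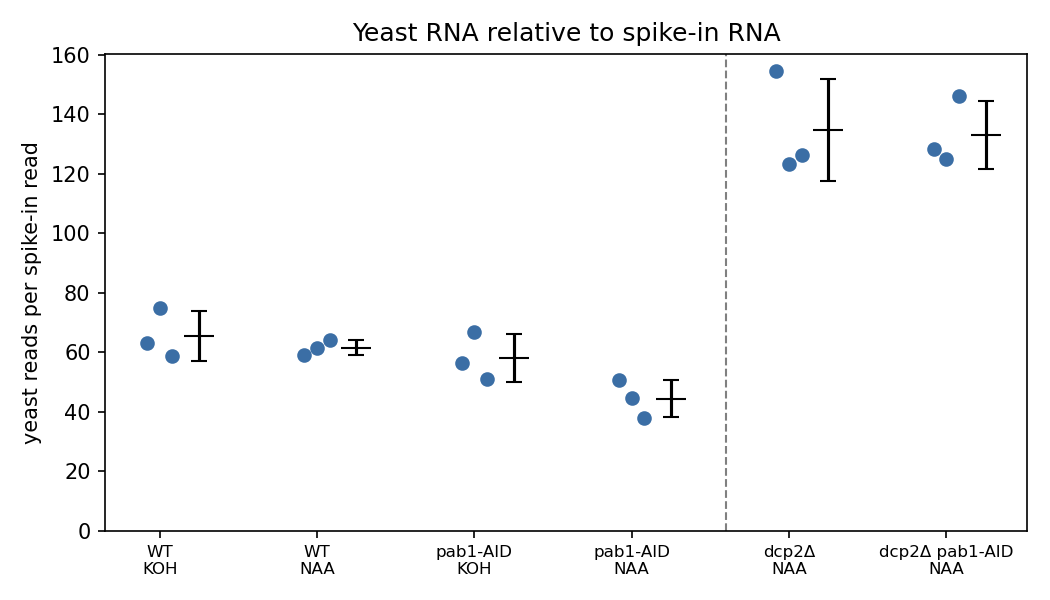
Yeast reads per spike-in read (vertical axis) in each RNA library (blue points), with the mean and SD of each group of 3 in black; the dashed line separates the 2 spike-in tables, which are not compared. The pab1-AID libraries in NAA average 44.4, against 61.5 for wild type in NAA.

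What NAA itself does was asked in wild-type cells. PDR12 (YPL058C), the plasma membrane exporter of weak acids, rose by a log2 change of 2.24 ± 0.18 (SE; edgeR, Benjamini-Hochberg adjusted p = 7.22e-07). The small heat shock genes HSP12 (1.94 ± 0.21) and HSP26 (1.31 ± 0.23) rose too. The sulfate permease genes SUL1 (YBR294W, chromosome II, 789235 to 791814) and SUL2 fell by 2.0 ± 0.17 and fell by 0.75 ± 0.13, and the hexose transporter gene HXT2 fell by 0.90 ± 0.15, the last not passing when only the compared groups were fitted. Of 29 general stress (Msn2/Msn4) genes 11 rose, 24 adjusted over the list alone, among them HSP12, GPH1, glycogen phosphorylase (0.77 ± 0.14), and YGP1 (0.73 ± 0.11), and none fell. Camera, a list test in limma, gave a Benjamini-Hochberg adjusted p of 1.58e-20 (adjusted p = 0.258 with an estimated correlation). Of 18 methionine and sulfur assimilation genes 6 fell and none rose, 11 and 0 adjusted over the list alone, with a median of -0.36. Examples were SUL1, SUL2, MMP1, an S-methylmethionine permease (-1.06 ± 0.15), and MET3, ATP sulfurylase (-0.55 ± 0.08). This call held (camera in limma, Benjamini-Hochberg adjusted p = 1.7e-17; adjusted p = 0.0244 with an estimated correlation). Of 19 drug and weak-acid efflux genes 3 rose, 6 rising and 1 falling adjusted over the list alone, PDR12 foremost. YOR1 lost its call without wild-type KOH replicate 1, 2 or 3 or wild-type NAA replicate 2 or 3, and RSB1 without wild-type KOH replicate 1. The list median of 0.06 turned to -0.02 under spike-in scaling (camera in limma, Benjamini-Hochberg adjusted p = 0.0258; adjusted p = 0.435 with an estimated correlation). In all, 163 genes rose and 96 fell of 6044 tested by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted 0.05 (1180 at unadjusted 0.05). The count was 1008 when only the compared groups were fitted, 457 with DESeq2 and 55 with spike-in totals as library sizes, and it was 70, 114 and 100 without wild-type KOH replicate 1, 2 or 3 and 139, 132 and 91 without wild-type NAA replicate 1, 2 or 3.

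The degron tag without NAA also had an effect of its own. HSP12 (1.93 ± 0.21), HSP26 (1.72 ± 0.23) and the glucose transporter gene HXT7 (1.67 ± 0.17) rose most, and RPS14B, a ribosomal protein gene (-1.53 ± 0.18), NDJ1, a meiotic telomere protein gene (-1.09 ± 0.12), and the low-affinity glucose transporter gene HXT1 (-1.04 ± 0.10) fell most. Here and for every comparison, the largest changes are those among genes at or above the median level whose replicate values do not overlap between the groups, which chance gives for 10% of genes with 3 against 3. Genes outside these limits can change more. Of 29 general stress genes 16 rose, 21 adjusted over the list alone, with GPH1 at 1.61 ± 0.14 (limma's camera, Benjamini-Hochberg adjusted p = 5.63e-16; adjusted p = 0.158 with an estimated correlation). Of 32 respiratory chain and ATP synthase genes 17 rose, 18 adjusted over the list alone, such as the ATP synthase genes ATP18 (0.73 ± 0.13), ATP16 (0.62), ATP1 (0.60) and ATP7 (0.60). In turn 14 of 22 ergosterol genes fell, 18 adjusted over the list alone, such as ERG3 (-0.56 ± 0.09), ERG1 (-0.55) and MVD1 (-0.51). These lists gave limma camera, Benjamini-Hochberg adjusted p = 2.06e-09 and 4.29e-09 (adjusted p = 0.152 for each with an estimated correlation), and neither list had a member going the other way. In edgeR 517 genes rose and 399 fell, 56.4% upward, against 44.3% of 1173 with DESeq2, 45.6% of 1000 with RLE size factors, and 415 genes in all with spike-in totals. The count of 916 became 1485 when only the compared groups were fitted and 553 without pab1-AID KOH replicate 1.

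Depletion of Pab1, the study's main question, was read as pab1-AID against wild type, both in NAA. It gave 2037 genes up and 2131 down of 6044 (edgeR). The largest rise among the genes named by rule was SUL1, from 0.957 ± 0.171 to 259.6 ± 8.91 CPM (log2 8.06 ± 0.17; edgeR, Benjamini-Hochberg adjusted p = 3.48e-20). It was followed by HBT1, a gene for shaping the mating projection (4.96 ± 0.14), STR3, a cystathionine lyase of methionine synthesis (4.68 ± 0.15), BOP2 (4.62 ± 0.16), the stress-inducible Hsp70 gene SSA3 (4.39 ± 0.12) and EMA35 (4.30 ± 0.21). RPS9A (YPL081W, chromosome XVI, 404950 to 406044), which encodes a protein of the small ribosomal subunit, fell most, from 104.8 ± 6.20 to 6.65 ± 2.12 CPM (-4.13 ± 0.13; edgeR, Benjamini-Hochberg adjusted p = 1.46e-17). The copper transporter gene CTR1 (-3.75 ± 0.22), the cell wall gene SUN4 (-3.70 ± 0.13), the daughter-cell wall glucanase gene DSE2 (-3.62 ± 0.10), the G1 cyclin gene PCL1 (-3.56 ± 0.18) and the histone H2B gene HTB2 (-3.55 ± 0.11) fell with it. Changes are relative to the middle of the distribution. With spike-in totals as library sizes the median gene moved by -0.82, and 576 genes rose and 3798 fell (13.2% upward, against 48.9%).

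Genes for making ribosomes and histones fell on depletion. All 135 cytosolic ribosomal protein genes measured fell, also 135 adjusted over the list alone, with a median of -1.48, for example RPS9A, RPS22B (-3.07 ± 0.12), RPL18B (-3.04 ± 0.15) and RPS21A (-2.88 ± 0.21). Of 65 mitochondrial ribosomal protein genes 59 fell, 59 adjusted over the list alone (median -1.14). Among them were RSM26 (-2.56 ± 0.19), MRPL51 (-1.98) and MRPL17 (-1.88). Ribosome biogenesis factors had 39 of 50 genes lower and 2 higher, 40 and 2 adjusted over the list alone (median -1.13), with the nucleolar genes NSR1 (-2.29 ± 0.13), NOP1 (-2.19) and the helicase gene DBP2 (-2.20). Translation initiation factors had 23 of 27 lower and 1 higher, 23 and 1 adjusted over the list alone (median -0.98), including PAB1 itself (-2.03 ± 0.07), SUI1, which encodes eIF1 (-2.02 ± 0.11), HCR1, a subunit of eIF3 (-1.90), and GCD11, the γ subunit of eIF2 (-1.83). PAB1, the tagged gene, was already at -1.04 with the tag alone. All 8 core histone genes fell, 8 adjusted over the list alone (median -2.31), such as HTB2, HTA2 (-3.43 ± 0.11) and HHT1 (-2.46). In this order limma's camera gave Benjamini-Hochberg adjusted p = 3.04e-47, 4.35e-08, 1.04e-08, 1.92e-08 and 3.04e-09, and adjusted p = 0.0818, 0.31, 0.341, 0.0803 and 0.0803 with an estimated correlation. With spike-in totals their medians were -2.28, -1.89, -1.93, -1.75 and -3.11.

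Genes of sulfur assimilation, stress, alternative carbon use and meiosis rose. Of 18 methionine and sulfur genes 14 rose and 1 fell, 14 and 1 adjusted over the list alone (median 1.38). Among them were SUL1, STR3 and the sulfite reductase genes MET10 (2.81 ± 0.11) and MET1 (2.64), the latter making its cofactor. Of 31 glucose-repressed genes 22 rose and 5 fell, 22 and 5 adjusted over the list alone (median 1.39). Examples were SFC1, a mitochondrial carrier (4.64 ± 0.75), ICL1, isocitrate lyase (3.91 ± 0.15), and the fatty-acid oxidation genes POX1 (3.83) and FOX2 (3.08). Of 29 general stress genes 21 rose and 2 fell, 23 and 2 adjusted over the list alone (median 1.21), with HSP12 at 3.52, NQM1 at 3.53 and the aldehyde dehydrogenase gene ALD3 at 3.31. HSP12 also rose with the tag alone. Of 23 meiosis and sporulation genes 17 rose and 1 fell, 19 and 1 adjusted over the list alone (median 1.46), such as the meiotic kinase gene MEK1 (3.85 ± 0.86) and DIT2, a spore wall gene (2.39). Amino acid biosynthesis (Gcn4) genes had 25 of 36 higher and 6 lower, 25 and 6 adjusted over the list alone, with SER3 (3.47 ± 0.095), LYS1 (2.94) and HIS4 (2.53). Their median of 0.61 turned to -0.20 with spike-in totals, where 11 rose and 13 fell. The other 4 lists kept a median above 0 there (0.59, 0.62, 0.40 and 0.67 in the order given). In the order of this paragraph limma's camera gave Benjamini-Hochberg adjusted p = 4.6e-11, 0.000444, 2.67e-05, 0.0217 and 2.97e-07, and adjusted p = 0.0803, 0.31, 0.434, 0.31 and 0.31 with an estimated correlation.

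**Figure D2:**
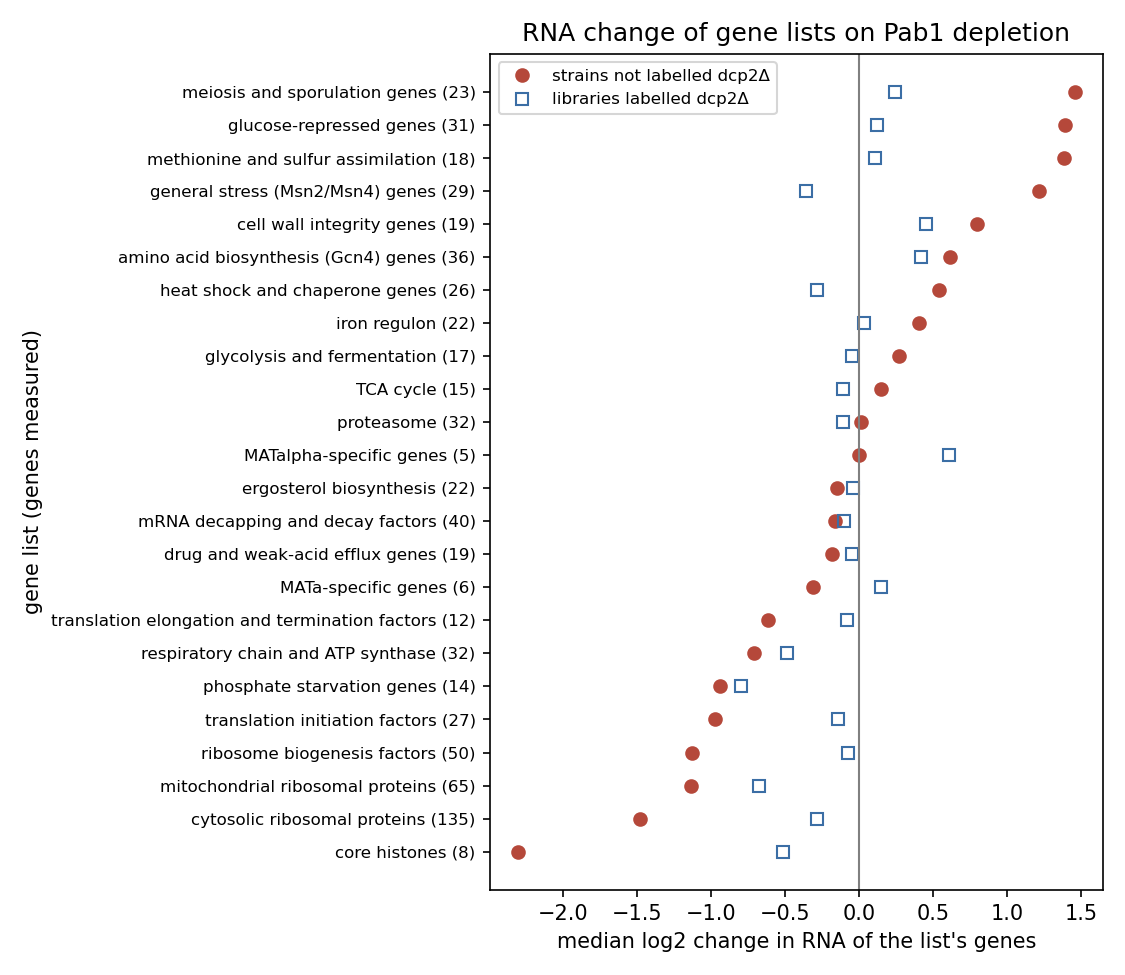
Median log2 change in RNA of the genes of each of 24 lists (number measured in brackets) on Pab1 depletion, in strains not labelled dcp2Δ (red points) and in libraries labelled dcp2Δ (blue open squares). Cytosolic ribosomal protein genes sit at -1.48 and -0.28, and the median of the Gcn4 list, 0.61 in those not labelled dcp2Δ, turns to -0.20 with spike-in totals as library sizes.

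The same depletion read within the tagged strain, NAA against KOH in pab1-AID, gave 2017 genes up and 2159 down of 6044 in edgeR. SUL1 (5.89 ± 0.15), BOP2 (4.59 ± 0.16) and HBT1 (4.46 ± 0.13) rose most and RPS9A (-4.14 ± 0.13), SUN4 (-3.60 ± 0.13) and DSE2 (-3.40 ± 0.10) fell most. With spike-in totals the median gene moved by -0.81 and 587 genes rose and 3813 fell (13.3% upward, against 48.3%).

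Footprints, which count ribosomes on coding sequences, followed on Pab1 depletion, with 2246 genes up and 2389 down of 5640 (edgeR). SUL1 (8.39 ± 0.12), SSA3 (7.29 ± 0.25) and HBT1 (7.13 ± 0.36) rose most, and HO, the mating-type switching endonuclease gene (-7.16 ± 0.21), PRY3, a cell wall protein gene (-5.17 ± 0.11), and TOS6, another (-4.97 ± 0.13), fell most. All 8 core histone genes fell, 8 adjusted over the list alone, led by HTB2 (-4.18 ± 0.067) and HTA2 (-3.23). In turn 17 of 18 methionine and sulfur genes rose while 1 fell, 17 and 1 adjusted over the list alone, with STR3 (5.05 ± 0.088), MET10 (3.68) and MET1 (3.19). Both calls held (limma's camera, Benjamini-Hochberg adjusted p = 1.86e-12 and 3.09e-12; adjusted p = 0.0495 for each with an estimated correlation).

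Relative translational efficiency, the footprint change less the RNA change, moved for 2199 of 5615 genes on Pab1 depletion, 1465 up and 734 down (edgeR), around a median of 0.11. HAC1 (YFL031W, chromosome VI, 75179 to 76147), which encodes the transcription factor of the unfolded protein response from an mRNA that needs splicing by Ire1, rose by 4.21 ± 0.18 (edgeR, Benjamini-Hochberg adjusted p = 6.9e-18). Its footprints were 42.1 ± 6.33 CPM in wild type and 1273 ± 33.3 in depleted cells, against RNA of 182.6 ± 6.43 and 292.9 ± 4.58. FIG2, an adhesin gene of mating cells (3.51 ± 0.23), SSA3 (2.87 ± 0.25) and the near-identical asparaginase genes ASP3-1, ASP3-2 and ASP3-4, whose reads cannot be told apart (2.22 ± 0.18), were the next largest within those limits. FIG2 also rose with the tag alone and was at 0.72 net of tag and NAA (edgeR, Benjamini-Hochberg adjusted p = 0.19). CRN1 (YLR429W, chromosome XII, 990777 to 992732), coronin of the actin cytoskeleton, fell most (-3.02 ± 0.11; edgeR, Benjamini-Hochberg adjusted p = 9.67e-22). Its footprints went from 207.9 ± 8.19 to 28.5 ± 4.48 and RNA from 104.0 ± 4.55 to 111.6 ± 1.64. In CAGE, given below, upstream tags of CRN1 fell and internal tags rose. Its RNA count therefore does not stand for the full-length mRNA alone, nor does its efficiency change. YKE4, a zinc transporter gene (-2.61 ± 0.21), the proton pump gene PMA2 (-2.38 ± 0.18), the forkhead transcription factor gene HCM1 (-2.13 ± 0.11), PRY3 (-1.97 ± 0.18) and the cell wall glucanase gene SCW11 (-1.96 ± 0.17) followed. Of 17 glycolysis and fermentation genes 16 rose, 16 adjusted over the list alone (median 0.56), such as the pyruvate decarboxylase gene PDC5 (1.03 ± 0.13), TDH2 (0.94) and PFK1 (0.72). Of 27 glucose-repressed genes 12 rose, 12 adjusted over the list alone (median 0.67), with ACS1, acetyl-CoA synthetase, at 2.88 ± 0.33 and IDP2 at 1.75. Of 22 ergosterol genes 14 rose, 17 adjusted over the list alone (median 0.29), such as HMG2 (0.82 ± 0.11) and ERG11 (0.67). No member of these lists fell, with limma camera, Benjamini-Hochberg adjusted p = 5.21e-05, 0.0418 and 0.0418 (adjusted p = 0.805 for each with an estimated correlation). Net of tag and NAA the count was 1236.

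In the controls, NAA in wild type changed the translational efficiency of 5 of 5615 genes (edgeR; 380 at unadjusted 0.05). Of these 4 are named after their values were seen. PRM7 (3.00), RTC6, a mitochondrial ribosomal protein gene (1.59), YHR214W-A (1.32) and YAR068W (1.29) rose. PAF1, a subunit gene of the Paf1 elongation complex named by rule, fell, at -0.55 ± 0.11 (edgeR, Benjamini-Hochberg adjusted p = 0.0273). The count was 3 and 2 without wild-type KOH replicate 1 or 3, and 0, 3 and 3 without wild-type NAA replicate 1, 2 or 3 (304 at unadjusted 0.05 without NAA replicate 1), 15 with DESeq2 and 36 when only the compared groups were fitted. Leaving out any library of either group ended the call of PAF1 (-0.56, -0.51 and -0.58 without KOH replicate 1, 2 or 3 and -0.61, -0.49 and -0.54 without NAA replicate 1, 2 or 3). The tag raised 9 genes, led by FIG2 (2.78 ± 0.25), SSA3 (1.47 ± 0.27) and RPS14B (1.42 ± 0.20), and lowered 8 (edgeR; 428 at unadjusted 0.05). The wall protein gene PIR3 (-1.03 ± 0.22) and ASP3-1 and ASP3-3 (-0.86 ± 0.19) fell most. RPS14B fell in RNA with the tag, as given above, so its efficiency change runs opposite to the RNA change that enters it. PIR3 lost its call without wild-type KOH replicate 1 or 3 (-0.75 and -1.08) or pab1-AID KOH replicate 1 or 3 (-0.88 and -1.02), and the ASP3 genes without wild-type KOH replicate 1 or 3 (-0.79 and -0.84) or pab1-AID KOH replicate 1 or 2 (-0.75 and -0.87). That count of 17 became 7 and 8 without wild-type KOH replicate 1 or 3 and 9 without pab1-AID KOH replicate 1, and 28 with DESeq2 and 68 when only the compared groups were fitted. SSA3 lost its call without KOH replicate 3 (1.44; edgeR, Benjamini-Hochberg adjusted p = 0.0519). With the footprint and RNA libraries of a number joined as 1 culture, the counts were 15 for NAA and 53 for the tag.

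Poly(A) tails were longer in pab1-AID than in wild type, both in NAA. The median over molecules was 41.0 ± 1.73 nt in wild type in NAA and 62.0 ± 1.00 nt in pab1-AID (SD, n = 3), a difference of 21 nt with all 3 depleted libraries above all 3 of wild type (two-sided exact permutation test, p = 0.1, the smallest possible). Molecules with tails under 25 nt dropped from 12.1 to 4.18%, and those over 80 nt grew from 3.18 to 18.4%. The mean tail rose for 2151 of 2175 genes and fell for none (limma; 2151 at unadjusted 0.05), by a median of 19.3 nt. The largest rise named by rule was in SCW4 (YGR279C, chromosome VII, 1048798 to 1049958), a cell wall glucanase gene, from 63.3 ± 4.88 to 114.6 ± 2.86 nt (51.4 ± 2.35; limma, Benjamini-Hochberg adjusted p = 6.1e-09). The glucan-modifying enzyme gene GAS5 went from 43.2 ± 0.835 to 87.1 ± 3.24 nt, the structural wall protein gene SED1 from 48.6 ± 1.15 to 84.7 ± 1.19 nt and UTH1 from 54.1 ± 4.83 to 89.8 ± 1.72 nt, beside the haem-binding protein gene DAP1 (37.8 ± 3.89) and HOR7 (35.5 ± 1.96). Tails of 129 of 132 ribosomal protein mRNAs rose, 129 adjusted over the list alone, by a median of 12.1 nt, less than the 19.3 nt of all genes. With each library centred their direction flips (-8.11 nt, 102 lower). RPS30B (25 ± 3.5 nt), RPL9B (23.3 nt) and RPS28B (22.8 nt) rose most, calls that did not pass with libraries centred. All 32 proteasome mRNAs rose, 32 adjusted over the list alone, by 23.4 nt, for example PRE2 (29.4 ± 2.6 nt), PRE6 (28.4 nt) and RPN6 (27.9 nt). Camera in limma gave Benjamini-Hochberg adjusted p = 8.26e-10 and 0.000184 for these lists, with adjusted p = 0.758 for each with an estimated correlation. Centred on each library, 170 genes were higher and 404 lower (29.6% upward, against 100.0%). All tail libraries are of cells in NAA, so the effect of the tag was not separated from that of depletion.

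**Figure D3:**
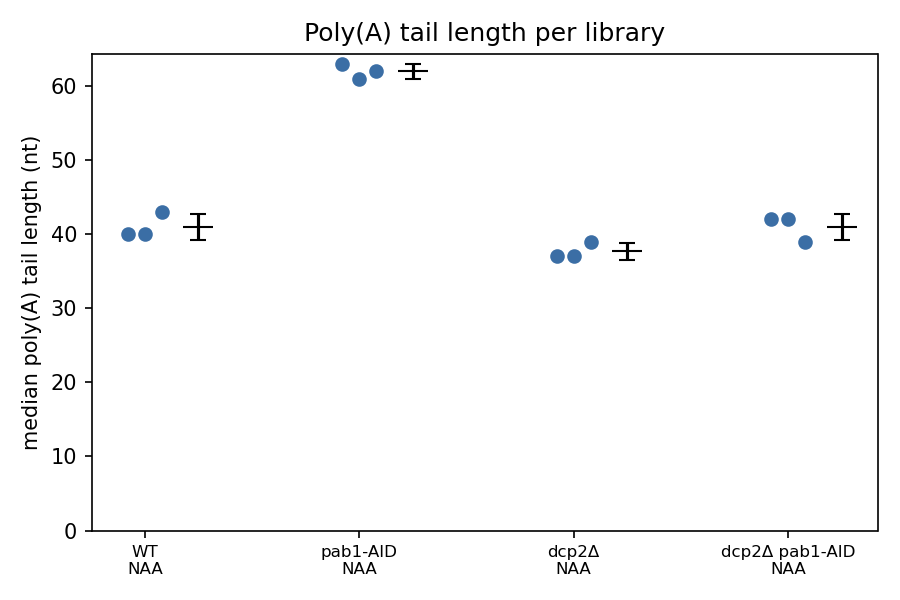
Median poly(A) tail length in nt over all molecules (vertical axis) in each SM-PAT library (blue points), with the mean and SD of each group of 3 in black. The pab1-AID libraries average 62.0 nt against 41.0 nt in wild type, and the dcp2Δ pab1-AID libraries 41.0 nt against 37.7 nt in dcp2Δ.

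The deletion of DCP2 that the labels name was read as libraries labelled dcp2Δ against wild type, both in NAA, with the difference in mating type given above. Beside MF(ALPHA)1, whose fitted change of 12.36 rests on a wild-type level near 0, RNA rose most for the transcription coactivator gene MBF1 (4.57 ± 0.12), the α2 repressor gene copies HMLALPHA2 and MATALPHA2, which share reads (4.41 ± 0.15), RPS28A (4.20 ± 0.19) and the peroxisome gene PEX34 (4.01 ± 0.24). In edgeR 2360 genes rose and 2110 fell of 6044. Beside AGA2, STE2 and BAR1 the largest falls were RPL42A, which shares reads with its copy (-4.30 ± 0.10), RPL32 (-4.24 ± 0.10) and the iron oxidase gene FET3 (-4.24 ± 0.52). Of 135 ribosomal protein genes 118 fell and 10 rose, the same numbers adjusted over the list alone (median -1.57), RPS28A going up and RPS29A (-3.80 ± 0.3) down. All 17 glycolysis and fermentation genes fell, 17 adjusted over the list alone (median -2.00), with TDH3 (-2.69 ± 0.11), FBA1 (-2.56) and HXK2 (-2.41). Of 29 general stress genes 25 rose and 1 fell (the same adjusted over the list alone; median 1.53), such as DCS2 (2.23). Of 23 meiosis genes 13 rose (13 adjusted over the list alone; median 1.18), such as REC8 (3.13) and IME2 (2.37). Phosphate starvation genes had 12 of 14 lower and 1 higher, the same adjusted over the list alone (median -1.14), with the phosphate transporter gene PHO84 (-3.29 ± 0.089) and the acid phosphatase genes PHO12 (-2.92) and PHO11 (-2.83). In this order limma's camera gave Benjamini-Hochberg adjusted p = 4.8e-33, 1.23e-13, 6.9e-05, 0.0391 and 8.84e-06, and adjusted p = 0.134, 0.137, 0.549, 0.263 and 0.0188 with an estimated correlation. Of these the phosphate list held.

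In footprints libraries labelled dcp2Δ had 1987 genes up and 1873 down of 5640 against wild type (edgeR), with the same mating-type split at the extremes. MF(ALPHA)1, HMRA2 (from 2.48 ± 0.303 to 115.3 ± 11.8 CPM) and HMLALPHA2 (from 6.98 ± 0.292 to 207 ± 20.1), the latter pair marked as sharing reads with copies, rose most. HMRA1 (27.9 ± 1.31 CPM in wild type and listed at 0 in dcp2Δ), the a-factor gene MFA2 (58.6 ± 1.99 and 0.0245 ± 0.0425) and STE2 fell most. Phosphate genes fell again, 13 of 14 with 1 rising and the same adjusted over the list alone, among them PHO12 (-3.40), PHO11 (-3.37) and PHO5 (-1.78). The call held (limma's camera, Benjamini-Hochberg adjusted p = 2.64e-18; adjusted p = 0.00072 with an estimated correlation). All 7 MATa-specific genes fell and all 5 MATalpha-specific genes rose, with 7 and 5 adjusted over the list alone (camera in limma, Benjamini-Hochberg adjusted p = 3.81e-43 and 1.26e-23; adjusted p = 3.52e-06 and 2.35e-05 with an estimated correlation). Translational efficiency rose for 1836 and fell for 1820 of 5615 genes (edgeR). RIB4, a riboflavin synthesis gene (3.89 ± 0.24), RPL42A (3.72 ± 0.11) and ADH2, which shares reads with a copy (3.70 ± 0.24), rose most, and RPS28A (-4.73 ± 0.19), STE2 (-4.57 ± 0.35) and MBF1 (-3.63 ± 0.14) fell most. RPS28A and MBF1 rose in RNA and RPL42A fell, as given above. Their efficiency changes thus run opposite to the RNA changes that enter them. Of 135 ribosomal protein genes 104 rose and 13 fell, 105 and 13 adjusted over the list alone (median 1.07). Of 17 glycolysis genes 16 rose, 17 adjusted over the list alone (median 1.58), such as PGK1 (2.28 ± 0.17) and TDH3 (2.19). For both lists the RNA fell (limma's camera for efficiency, Benjamini-Hochberg adjusted p = 1.55e-20 and 6.66e-13; adjusted p = 0.328 and 0.24 with an estimated correlation). Tails were 37.7 ± 1.15 nt in libraries labelled dcp2Δ, 3.33 nt shorter than in wild type by the median over molecules (-3.33, exact p = 0.1). The mean tail fell for 335 genes and rose for none (limma; 818 at unadjusted 0.05), CPA1 (-17.5 ± 3.16 nt), CSS1 with shared reads (-14.9 ± 2.26 nt) and MIC12 (-14.7 ± 2.65 nt) most. That count was 16, 22 and 203 without dcp2Δ replicate 1, 2 or 3 and 214 and 116 without wild-type replicate 2 or 3, and 563 on the log2 of the mean (1 of them rising). Without dcp2Δ replicate 1 or 2 MIC12 no longer passed (-14.0 and -13.6 nt), and with each library centred no gene passed in limma (313 at unadjusted 0.05).

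Pab1 depletion was also read in the libraries labelled dcp2Δ, as dcp2Δ pab1-AID against dcp2Δ, which share the α pattern. RNA rose for 724 and fell for 712 of 6044 genes (edgeR). SNZ1 (YMR096W, chromosome XIII, 458408 to 459301), a vitamin B6 synthesis gene, rose from 9.78 ± 0.275 to 35.4 ± 2.61 CPM (1.86 ± 0.11; edgeR, Benjamini-Hochberg adjusted p = 1.64e-10). BOP2 (1.80 ± 0.14), HXT1 (1.74 ± 0.11), the arginine synthesis gene ARG1 (1.52 ± 0.11), ARO5 (1.29 ± 0.09) and the histidine synthesis gene HIS4 (1.23 ± 0.10) followed. PHO84 (YML123C, chromosome XIII, 24037 to 25800) fell from 159.9 ± 5.74 to 41.4 ± 4.69 CPM (-1.95 ± 0.09; edgeR, Benjamini-Hochberg adjusted p = 4.14e-13), ahead of the polyamine exporter gene TPO1 (-1.46 ± 0.16), the decapping enhancer gene EDC1 (-1.42 ± 0.10), the acid phosphatase gene PHO5 (-1.33 ± 0.11), the polyphosphate synthesis gene VTC1 (-1.29 ± 0.20) and the glycerophosphoinositol permease gene GIT1 (-1.22 ± 0.10). With spike-in totals the median gene moved by -0.15, and 43 genes rose and 148 fell (22.5% upward, against 50.4%). The count of 1436 genes was 908 when only the compared groups were fitted. With dcp2Δ pab1-AID replicates 1 and 2 and dcp2Δ replicate 2 set against the other libraries of the pair, 459 genes were called. These libraries also had the higher shares of counts in reading frames of the ribosomal DNA locus. A difference between libraries that crosses the groups thus ran through this comparison and was not modelled.

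Mitochondrial ribosomal protein and phosphate genes fell in that comparison and cell wall and amino acid genes rose. Of 65 mitochondrial ribosomal protein genes 55 fell and none rose, 62 and 0 adjusted over the list alone (median -0.68, with MRPL31 at -1.23 ± 0.18 and MRP4 at -0.89). Of 14 phosphate starvation genes 8 fell and 1 rose, 10 and 3 adjusted over the list alone (median -0.80), such as PHO84, PHO5 and SPL2 (-1.87 ± 0.22). Of 19 cell wall integrity genes 12 rose, 12 adjusted over the list alone (median 0.45), such as YPS3 (1.20 ± 0.10), the glucan synthase gene GSC2 (0.95) and the transglycosylase gene CRH1 (0.92). These 3 calls held (limma's camera, Benjamini-Hochberg adjusted p = 2.81e-31, 1.03e-15 and 1.33e-10; adjusted p = 0.00114, 0.000263 and 0.0276 with an estimated correlation). Amino acid biosynthesis genes rose for 26 of 36, 32 adjusted over the list alone (median 0.41), such as ARG1, HIS4 and ARG3 (0.97 ± 0.1). Ribosomal protein genes fell for 62 of 135 with 1 rising, 77 and 1 adjusted over the list alone (median -0.28), such as RPS17B (-0.72 ± 0.12) and RPL25 (-0.59). For these lists camera in limma gave Benjamini-Hochberg adjusted p = 1.1e-19 and 1.73e-13 (adjusted p = 0.0558 and 0.34 with an estimated correlation). With spike-in totals 30 mitochondrial and 6 phosphate genes fell and 3 cell wall and 4 amino acid genes rose in edgeR, while RPS17B and RPL25 no longer passed (list median -0.41).

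Footprints in libraries labelled dcp2Δ pab1-AID against dcp2Δ rose for 1689 and fell for 1701 of 5640 genes (edgeR). SNZ1 (3.18 ± 0.11), SUL1 (1.68 ± 0.32) and SAG1 (1.65 ± 0.13) rose most, and GIT1 (-2.41 ± 0.09) and PHO84 (-1.98 ± 0.06) fell ahead of FET3 (-1.94 ± 0.78). The call of FET3 was lost without dcp2Δ replicate 2 (-1.12) or without dcp2Δ pab1-AID replicate 1, 2 or 3 (-1.82, -2.22 and -1.87). Of 65 mitochondrial ribosomal protein genes 64 fell, 65 adjusted over the list alone (median -0.88), such as MRPL8 (-1.55 ± 0.076). Of 14 phosphate genes 10 fell and 1 rose, 10 and 1 adjusted over the list alone. Both calls held (limma's camera, Benjamini-Hochberg adjusted p = 2.68e-47 and 1.04e-09; adjusted p = 0.00756 and 0.0176 with an estimated correlation). Translational efficiency rose for 514 and fell for 162 of 5615 genes (edgeR). SNZ1 (1.32 ± 0.16), GCN4, which encodes the activator of amino acid synthesis and is under translational control (1.25 ± 0.15), IRA1, a Ras inhibitor gene (1.15 ± 0.14), CDC39, which encodes the Not1 scaffold of the deadenylase complex (1.05 ± 0.10), TAO3 (1.02 ± 0.12) and BPH1 (1.01 ± 0.18) rose most. The drug pump gene PDR15 (-1.78 ± 0.26), GIT1 (-1.19 ± 0.14), the cell wall sensor gene WSC4 (-1.09 ± 0.22), CLG1 (-0.97 ± 0.15), SFG1 (-0.95 ± 0.15) and CRN1 (-0.90 ± 0.10) fell most. Of the mitochondrial ribosomal protein genes 8 fell further in efficiency, 8 adjusted over the list alone (median -0.17), with MRPL8 at -0.69 and MRP20 at -0.57 (limma's camera, Benjamini-Hochberg adjusted p = 3.1e-08; adjusted p = 0.249 with an estimated correlation). The count of 676 genes was 439 and 392 without dcp2Δ pab1-AID replicate 1 or 2, and 264 when only the compared groups were fitted. The split across the groups that called 459 genes in RNA called 60 in efficiency.

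Tails in libraries labelled dcp2Δ pab1-AID were 41.0 ± 1.73 nt by the median over molecules against 37.7 ± 1.15 nt in dcp2Δ, a difference of 3.33 nt (two-sided exact permutation test, p = 0.2). By the median over genes the difference was 1.53 nt (exact p = 0.3). The mean tail rose for 4 of 2175 genes and fell for none in limma (315 at unadjusted 0.05). These were SCW4, from 58.7 ± 1.18 to 114.6 ± 1.78 nt (55.8 ± 2.35; limma, Benjamini-Hochberg adjusted p = 2.22e-09), GAS5 (13.4 ± 2.09 nt), and, named after their values were seen, YNL190W (19.4 ± 2.14 nt) and YDR524W-C (12.4 nt). Leaving out any of these 6 libraries moved the count, to 2 for each of the dcp2Δ replicates and for dcp2Δ pab1-AID replicates 1 and 2, and to 15 for replicate 3. It was 22 for genes with at least 50 molecules and 19 on the log2 of the mean. GAS5 lost its call without any of the first 5 (13.2, 13.1, 13.9, 13.5 and 12.5 nt).

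Whether the effect of Pab1 depletion differs between strains not labelled dcp2Δ and libraries labelled dcp2Δ was tested as the difference of the 2 effects. In RNA it differed for 3125 of 6044 genes, 1588 upward and 1537 downward (edgeR). Of 135 ribosomal protein genes 133 had a less negative effect in libraries labelled dcp2Δ (median 1.18; 133 adjusted over the list alone), such as RPS9A (3.77 ± 0.16), RPL18B (2.98) and RPS29A (2.74). In turn 25 of 29 stress genes and 14 of 18 methionine and sulfur genes had a lower effect there (25 and 14 adjusted over the list alone), with 2 and 1 going the other way. Examples were HSP12 (-4.41 ± 0.28), ALD3 (-3.36), SUL1 (-7.44 ± 0.25) and STR3 (-4.85). Camera in limma gave Benjamini-Hochberg adjusted p = 3.4e-40, 1.9e-09 and 6.93e-13 (adjusted p = 0.117, 0.4 and 0.0781 with an estimated correlation). In translational efficiency 907 of 5615 genes differed, 365 upward and 542 downward (edgeR; median -0.07), with 12 of 17 glycolysis genes lower, 15 adjusted over the list alone, with TDH2 at -0.94 ± 0.16 and PFK1 at -0.71 (limma's camera, Benjamini-Hochberg adjusted p = 2.62e-07; adjusted p = 0.697 with an estimated correlation). The tail effect was smaller in libraries labelled dcp2Δ for 2019 of 2175 genes and larger for none (limma; 2022 at unadjusted 0.05; median -17.7 nt), a difference of -17.7 nt also between the library medians (two-sided exact permutation test over 400 arrangements, p = 0.1). Relative to each library's own median over genes 259 genes were higher and 61 lower (80.9% upward, against 0). The strain pairs also differ from each other in mating-type pattern, RNA depth and spike-in table, so batch and strain cannot be told apart. PAB1 RNA was already low in dcp2Δ, at 147 CPM against 957 in wild type (log2 -2.70). Its change was -0.72 in libraries labelled dcp2Δ and -2.03 in the other pair, so the contrast in PAB1 differs too. Pab1 protein was not measured. DCP2 reads were seen on both sides while the HIS3 marker rose, and neither shows whether functional Dcp2 was lost. The differences therefore cannot be assigned to Dcp2.

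Across genes, the effects in strains not labelled dcp2Δ and in libraries labelled dcp2Δ, which share no library, ran in the same direction for 68.1% of 6044 genes in RNA (Spearman rho 0.491, jackknife SE 0.0498; slope 0.143 ± 0.0234) and for 62.1% of 5615 in translational efficiency (rho 0.361, SE 0.0593; slope 0.156 ± 0.0138). For genes with a mean CPM above the median the slope in efficiency was 0.286 (rho 0.480). Genes are not independent replicates, so no p is given. The change in efficiency on Pab1 depletion was unrelated in rank to the efficiency in wild-type KOH libraries (rho -0.000219, SE 0.0461) and rose with coding length (rho 0.181, SE 0.0359; 5611 genes).

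Capped 5′ ends upstream of genes gave a second measure of mRNA change on Pab1 depletion. Tags rose for 2004 and fell for 2442 of 5642 genes (limma; median -0.06). Which direction prevailed turned with the test, with 2293 up and 2099 down by DESeq2 on recovered tags (median 0.06) and 2254 and 2150 by edgeR (median 0.03), the latter added after the data were seen. PMC1 (YGL006W, chromosome VII, 485921 to 489442), the vacuolar calcium pump, went from 4.14 ± 0.832 to 210.4 ± 15.4 TPM (5.21 ± 0.10; limma, Benjamini-Hochberg adjusted p = 6.93e-18). ALD3, which shares reads with a copy, rose by 4.85 ± 0.11, and the Rab GTPase-activating gene GYP7 by 4.39 ± 0.08. PRY3 fell from 51 ± 1.13 to 0.911 ± 0.348, RPS9A from 411.8 ± 11.7 to 20.02 ± 1.13 and DSE2 from 266.9 ± 9.02 to 18.8 ± 0.998 TPM. Of 137 ribosomal protein genes 131 fell and 5 rose, the same adjusted over the list alone (median -1.36), with RPS26A going up (3.98 ± 0.2). Of 29 stress genes 26 rose and 3 fell, also adjusted over the list alone (median 1.73), such as HSP12 (3.77) and GRE1 (3.50). Camera in limma gave Benjamini-Hochberg adjusted p = 3.24e-18 and 1.47e-07 (adjusted p = 0.167 and 0.119 with an estimated correlation).

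Capped 5′ ends inside coding sequences asked whether transcripts also start within genes. Their share of gene-assigned tags was 1.96 ± 0.0226% in wild type and 5.13 ± 0.462% on Pab1 depletion (SD, n = 3), every depleted library being higher (two-sided exact permutation test, p = 0.1). Positions with 2 tags are listed only in depleted replicates 2 and 3, and the difference of 3.17 points was 2.70 at positions with at least 3 tags and 1.70 with at least 10. The share was 2.25 ± 0.114 and 23.5 ± 0.622% for the spt6 mutant and 1.60 ± 0.0826 and 2.99 ± 0.601% for set1Δ set2Δ (n = 2; exact p = 0.333 each, the smallest possible). The difference of 1.39 points for set1Δ set2Δ was 0.757 at positions with at least 10 tags, a setting added after the data were seen. Relative to each gene's own upstream tags, internal tags rose for 3431 and fell for 381 of 4932 genes on Pab1 depletion (limma; median 1.22). In settings mostly added after the data were seen, that median depended on the pseudocount and test, with 0.65 and 1.97 at pseudocounts of 4 and 0.25 and 3.35 and 3.50 with DESeq2 and edgeR on recovered tags, and the falls ran from 719 at a pseudocount of 4 to 197 with edgeR. With only the compared groups fitted, fewer genes were tested, and 2408 of 2780 were called (median 1.80). The 4932 genes had been filtered over all CAGE libraries, the chromatin mutants included. In this test a fall of upstream tags alone counts as a rise of internal tags. PAB1 was called at 1.64 with internal tags at 2.87 TPM in wild type and 2.98 in depleted cells. Its upstream tags went from 665 to 212 TPM. RPS30A (YLR287C-A, chromosome XII, 712537 to 713158; the span holds its intron) went from 0.725 ± 0.25 to 94.4 ± 8.68 internal TPM (8.79 ± 0.23; limma, Benjamini-Hochberg adjusted p = 3.37e-19). CRN1 went from 5.81 ± 0.34 to 167 ± 3.61 while its upstream tags fell from 85.7 ± 4.99 to 7.52 ± 1.76. PRE8 (YML092C, chromosome XIII, 85987 to 86739), a proteasome subunit gene (7.76 ± 0.27), TCD1, a tRNA modification gene (7.34 ± 0.23), HCR1 (7.04 ± 0.31) and the ubiquitin receptor gene DSK2 (6.87 ± 0.19) completed the 6 largest. Both CAGE groups of this pair were in NAA, so here too the tag was not separated from depletion.

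In the chromatin mutants internal tags relative to upstream tags rose for 4542 and fell for 152 of 4932 genes in the spt6 mutant (limma; median 4.10), where upstream tags of the median gene were at -0.71. In set1Δ set2Δ they rose for 2057 and fell for 225 (median 0.60; 0.37 without set1Δ set2Δ replicate 1 and 0.87 without replicate 2). That median was 1.59 with DESeq2 on recovered tags and, in settings added after the data were seen, 1.54 with edgeR on them and 0.33 and 0.95 at pseudocounts of 4 and 0.25. A fall of upstream tags alone counts as such a rise. SET1 was called at 4.81 in set1Δ set2Δ with internal tags listed at 0 in both groups, and SET2 at 1.10 with internal tags going from 2.71 TPM to 0. The largest relative rises in the spt6 mutant were in PRE8 (8.43 ± 0.33), the proteasome ATPase gene RPT6 (8.32 ± 0.31), the proline synthesis gene PRO2 (8.28 ± 0.34), SPT6 itself (8.03 ± 0.41), the ubiquitin protease gene UBP14 (8.02 ± 0.29) and the flippase gene DNF1 (8.00 ± 0.29). In set1Δ set2Δ they were in STE11 (YLR362W, chromosome XII, 849866 to 852019), a kinase of the mating pathway, from 0.255 ± 0.143 to 57.6 ± 3.42 TPM (6.39 ± 0.29; limma, Benjamini-Hochberg adjusted p = 2.3e-14), the Hsp70 gene SSA4 (5.94 ± 0.30), the sterol regulator gene ECM22 (5.81 ± 0.29), the kinase gene RIM15 (5.63 ± 0.25), the urea-degrading enzyme gene DUR12 (5.58 ± 0.30) and the sterol transfer gene LAM5 (5.44 ± 0.30). The naming rule asks that both mutant libraries lie apart from both of their wild type. With 2 against 2, chance gives this in either direction for a share of 0.333 of genes.

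**Figure D4:**
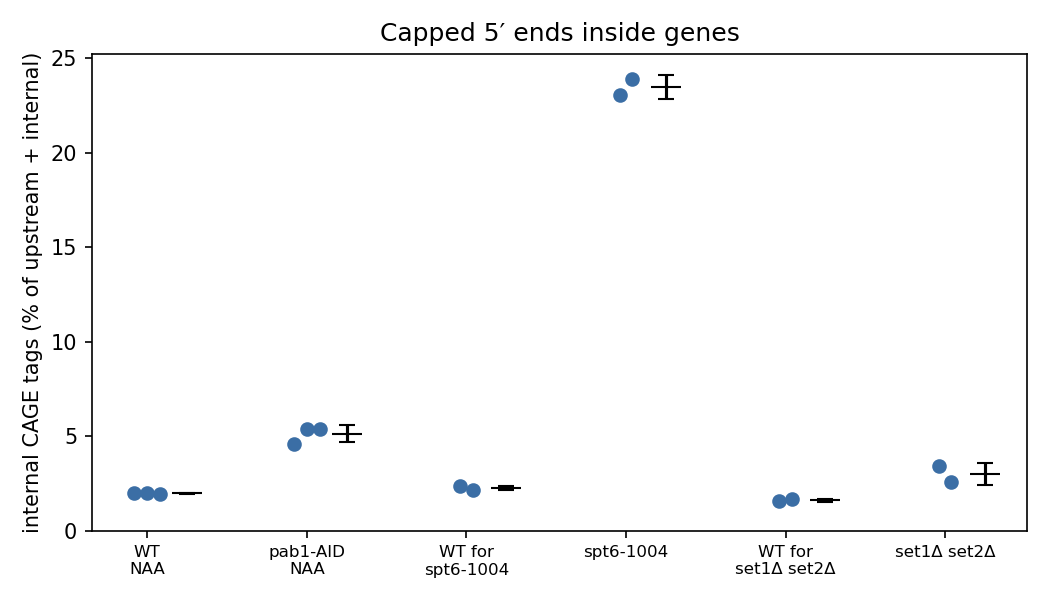
Share of CAGE tags inside coding sequences, in % of upstream and internal tags (vertical axis), in each library (blue points), with the mean and SD of each group in black. Wild-type groups average 1.60 to 2.25%, pab1-AID in NAA 5.13%, the spt6 mutant 23.5% and set1Δ set2Δ 2.99%.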

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

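The share of other splits was set as a test before the result was seen, the look at which splits kept a strain pair whole was chosen only after it, and the antisense shares carry no test. The effect of Pab1 depletion differed between strains not labelled dcp2Δ and libraries labelled dcp2Δ for 3125 genes in RNA, 907 in translational efficiency and 2019 in tail length, each by a test of the difference itself (edgeR for the first pair, limma for tails). The strain pairs also differ from each other in mating-type pattern, RNA depth, spike-in table and the size of the PAB1 change. The design does not separate these from the deletion that the labels name. DCP2 reads were present on both sides, which does not show whether functional Dcp2 was lost. Among 100 drawn splits of the RNA libraries 10, the real one included, gave as many genes as 3125, with 3929 in the highest other. In tails 10 of 100 splits gave as many as 2019, with 2137 in the highest other, and in translational efficiency 4 of 100 gave as many as 907, with 2013 in the highest other. The bound set beforehand, fewer than 5 of 100, was met in efficiency and not in RNA or tails. The splits with as many genes kept at least 1 strain pair whole, and with it that pair's effect of Pab1 depletion, so these shares are set by that structure of the samples and neither exclude chance for the differences nor speak for it.

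CAGE tags on the strand opposite to genes are outside the comparisons above. At positions with at least 3 tags their share was 0.608% in pab1-AID in NAA against 0.172% in wild type, and every depleted library lay above every control library. It was 7.52% in the spt6 mutant against 0.541% in its wild type, and 0.791% in set1Δ set2Δ against 0.324%, with each mutant library above both controls. No explanation for these shares was tested.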

How the results depend on the processing

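Settings chosen only after the data were seen are named as added, and they include all tests that leave out libraries for the agreement and coding length relations. Among named genes 6227 of the values under other settings had the direction and the side of the threshold of the main value, 149 no longer passed, 36 came to pass and 10 reversed. Among main values and counts 471 stayed within the spread or within 1.5 times and 100 moved. Where values moved, the cause was not tested, except that fewer genes or samples enter stricter filters and smaller fits.

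A minimum log2 change of 1 left 23 genes for RNA NAA in WT, 118 for RNA tag, 1780 for RNA Pab1 depletion, 1812 for RNA NAA in pab1-AID, 2121 for RNA dcp2 deletion, 59 for RNA Pab1 depletion in dcp2 and 1279 for RNA difference of Pab1 depletion effects. It left 2146 for Ribo Pab1 depletion, 658 for Ribo dcp2 deletion and 310 for Ribo Pab1 depletion in dcp2. For TE tag it left 10, for TE Pab1 depletion 492, for TE dcp2 deletion 1506, for TE Pab1 depletion in dcp2 45 and for TE difference of Pab1 depletion effects 283. Fitting only the groups compared gave 1008 for RNA NAA in WT, 1485 for RNA tag, 908 for RNA Pab1 depletion in dcp2, 36 for TE NAA in WT, 68 for TE tag, 264 for TE Pab1 depletion in dcp2 and 2408 for internal CAGE genes Pab1 depletion. Spike-in totals as library sizes gave 55 for RNA NAA in WT, 415 for RNA tag and 191 for RNA Pab1 depletion in dcp2. DESeq2 gave 457 for RNA NAA in WT, 15 for TE NAA in WT and 28 for TE tag. A mean of at least 50 counts gave 1 for TE NAA in WT. Net of tag and NAA, TE Pab1 depletion had 1236 genes.

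For tail length Pab1 depletion 3354 genes passed with at least 10 molecules, 896 with at least 50 and 574 with each library centred. For tail length dcp2 deletion 563 passed on the log2 of the mean and 0 with libraries centred (limma; 313 at unadjusted 0.05). For tail length Pab1 depletion in dcp2 the counts were 2 with at least 10 molecules, 22 with at least 50 and 19 on the log2 of the mean, and for tail length difference of Pab1 depletion effects 856 with at least 50 molecules and 320 centred. By the mean over molecules the median tail length Pab1 depletion became 17.9 nt and the median tail length difference of Pab1 depletion effects -14.9 nt. The median over genes gave 1.53 nt for median tail length Pab1 depletion in dcp2. Of the list tests 14 passed with an estimated correlation and 287 by fry.

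The internal CAGE share Pab1 depletion was 3.51 points with internal tags from nearer the start and 2.70 at positions with at least 3 tags, and with added settings 1.70 with at least 10, 2.13 with at least 3 in every library of the group and 2.71 thinned to one depth. The share in the spt6 mutant was higher by 19.8 points with internal tags from farther inside, 22.4 from nearer the start, 21.96 with a narrower upstream window and 20.6 with a wider one. The added settings gave 16.96 with at least 10 tags, 19.9 with at least 3 tags in every library and 20.3 thinned. The internal CAGE share set1 set2 was 0.757 points with at least 10 tags. The RNA rho of the Pab1 depletion effects in strains not labelled dcp2Δ and in libraries labelled dcp2Δ was 0.578 over genes called in the former. The TE rho was 0.551 over such genes and 0.480 for genes with CPM above the median, where the slope was 0.286.

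Replicate numbers did not pair the libraries across groups. Deviations of same-numbered libraries correlated at 0.0228 on average in RNA (-0.0967 to 0.359) and at -0.000536 in footprints (-0.183 to 0.182). Footprint and RNA libraries of the same group and number correlated at 0.105 on average over 18 pairs (-0.0287 to 0.451). Different numbers were not compared for them, so whether a number joins both libraries of a culture is not settled. In a check added after the data were seen the 3 same-numbered pairs of tail libraries correlated at 0.0244 or lower for dcp2Δ against wild type (lowest -0.0804), and on average at 0.00506 for Pab1 depletion and -0.00803 in dcp2Δ. In CAGE on Pab1 depletion the average was 0.0332 upstream and 0.00495 internal. In the spt6 mutant it was 0.248 and 0.0953 and in set1Δ set2Δ 0.0707 and -0.0822, with 2 pairs each, too few to pair them. With the replicate block tail length dcp2 deletion had 167 genes and tail length Pab1 depletion in dcp2 had 2. With the culture replicate block TE NAA in WT had 15 and TE tag 53. Other counts stayed within 1.5 times, such as 4189 for RNA Pab1 depletion, and so did the 181 list tests.

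With each replicate left out in turn the counts ran from 70 to 139 for RNA NAA in WT, 553 to 762 for RNA tag, 0 to 4 for TE NAA in WT (edgeR; 0 without wild-type NAA replicate 1, with 304 at unadjusted 0.05), 7 to 15 for TE tag, 392 to 997 for TE Pab1 depletion in dcp2, 16 to 401 for tail length dcp2 deletion and 2 to 15 for tail length Pab1 depletion in dcp2. Agreement ran from 0.433 to 0.513 for the RNA rho, 0.297 to 0.386 for the TE rho and 0.127 to 0.164 for the TE slope, and the relation with coding length from 0.143 to 0.1998. Counts moved by over 1.5 times without any of the libraries for RNA NAA in WT, without pab1-AID KOH replicate 1 for RNA tag (553), without dcp2Δ pab1-AID replicate 1 (439) or 2 (392) for TE Pab1 depletion in dcp2, and without dcp2Δ replicate 1 (16), 2 (22) or 3 (203) or wild-type NAA replicate 2 (214) or 3 (116) for tail length dcp2 deletion.

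Reversed values were RNA Pab1 depletion DCP2 at -0.43, RNA NAA in pab1-AID HIS3 at -0.026 and RNA NAA in pab1-AID DCP2 at -0.30 with spike-in totals. With libraries centred tail length Pab1 depletion SPT6 was at -9.61 nt and tail length difference of Pab1 depletion effects SPT6 at 4.84 nt. On recovered tags internal CAGE genes Pab1 depletion SET2 was at -0.078 with DESeq2 and -0.060 with edgeR (added), and internal CAGE genes set1 set2 SET2 at -4.23 and -4.86, and at -0.26 with an added pseudocount of 0.25. The cause was not tested.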

Other observations

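The settings of at least 3 tags and of the median over genes were planned, but their use as tests of an explanation, and the tests by thinned depth and by the scaled amount of long tails, were chosen only after the result was seen. The RNA of 4168 genes changed on Pab1 depletion. The labels do not say whether the mRNA kit captures tails. If capture of lengthened tails set the differences between genes, RNA and tail changes would rise together. Across the 2139 genes with both changes tested the Spearman rho was -0.0142. Tails rose for 2151 of 2175 genes, so a capture bias acting alike on all genes would not show in this rho. Whether such a bias entered the RNA counts or the spike-in ratio was not tested. If the change belonged to the RNA libraries and not to the mRNAs, CAGE would not follow it, and the rho with upstream CAGE changes was 0.854 over 5512 genes. Leaving out the shallow pab1-AID NAA replicate 2 gave 4066 genes. A change in mRNA levels with loss of Pab1 may explain it, as a hypothesis, while the differing preculture stays open and untested, and the tag in KOH changed 916.

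The higher internal CAGE share on Pab1 depletion was seen with either correction for low positions or depth: the lowest depleted library lay above the highest wild-type library by 2.62 points at positions with at least 3 tags and by 2.61 points after thinning. Whether these ends arise at the sites used in the spt6 mutant cannot be told from changes per gene, which hold no positions within a gene. The rho of those changes across 4932 genes was 0.229, between the bounds set for either reading before it was computed. Genes whose internal tags rose relative to their upstream tags, a set that also holds genes whose upstream tags fell alone, had a median log2 efficiency change of 0.07 against 0.25 in genes matched on RNA and CAGE level, a difference of -0.187 that also lies between its bounds (bootstrap SD 0.0137 over genes, which leaves out the spread between cultures, and the matched set of 3408 reuses 1136 different genes), so that less translated internal RNAs could contribute but were not shown to. Other sources of these ends were not tested, and both CAGE groups were in NAA, which does not separate the tag from depletion.

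A change in which genes were sampled did not account for longer tails on Pab1 depletion, since the median over genes, each with equal weight, differed by 20.5 nt. Loss of short-tailed molecules alone would not raise the amount with tails over 80 nt. The share over 80 nt in the tail libraries, scaled by the spike-in ratio of the RNA libraries, rose by a log2 of 2.07. Spike-in counts were listed for RNA libraries only, so this amount joins separate assays. What lengthens them stays open, since all tail libraries were in NAA, which does not separate the tag from depletion, and the differing preculture and a bias of the tail assay by length were not tested.

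For each comparison of 3 against 3 only 10 splits exist and the real one is 1 of them, too few for a share under 0.05. The real and highest other counts in RNA were 259 and 1 for NAA in wild type, 916 and 0 for the tag, 4168 and 0 for Pab1 depletion, 4176 and 1 for NAA in pab1-AID, 4470 and 0 for dcp2Δ and 1436 and 459 for Pab1 depletion in dcp2Δ. In footprints they were 4635 and 0 for Pab1 depletion, 3860 and 0 for dcp2Δ and 3390 and 0 for Pab1 depletion in dcp2Δ. In translational efficiency they were 5 and 1 for NAA, 17 and 0 for the tag, 2199 and 1 for Pab1 depletion, 3656 and 0 for dcp2Δ and 676 and 60 for Pab1 depletion in dcp2Δ. In tails they were 2151 and 0, 335 and 0, and 4 and 0 for Pab1 depletion, dcp2Δ and Pab1 depletion in dcp2Δ, and in CAGE on Pab1 depletion 3812 and 0 for internal and 4446 and 0 for upstream tags. The splits with 459 and 60 both set dcp2Δ pab1-AID replicates 1 and 2 with dcp2Δ replicate 2. Reading frames of the ribosomal DNA locus took 8.22, 9.34 and 10.3% of counts there. In dcp2Δ pab1-AID replicate 3 and dcp2Δ replicates 1 and 3 they took 4.42, 4.69 and 5.70%. This difference crosses the groups and was not modelled, and its cause was not tested.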
